A study of Caenorhabditis elegans with 10 samples.

How the data were processed

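The series holds 10 RNA-seq libraries from hand-dissected germline tumours of Caenorhabditis elegans, 5 from worms with an active GLP-1 Notch receptor (GLP-1 ON) and 5 from worms without it (GLP-1 OFF). Per the labels' protocols, bleach-synchronised L1 larvae were grown for 48 h at 25 °C, germlines were cut away from the bodies of adults on day 1 of adulthood, total RNA was extracted with Trizol, ribosomal RNA was depleted and libraries were made with the Kapa hyper prep kit. The series' design text describes the 5 libraries of a group as biological replicates. Groups and replicate numbers were taken from the sample titles, and table columns were matched to samples through the sample numbers in the labels.

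The authors deposited 1 table of gene-level values for all 10 libraries. Per the submitters' processing notes, the tools were STAR 2.0.4b, featureCounts 1.4.5 from Subread, edgeR and limma. The genome build, the annotation release, the use of strand in counting and the treatment of reads that match several genes are not given in the sources used here. The deposited signal is the authors' CPM, scaled to a fixed total of reads assigned to genes. The table has 46998 rows, of which 462 repeat a gene identifier with the same values, leaving 46536 genes. After removal of the repeats a library falls short of the CPM total by 0.137% to 0.196%, so a small part of the counted reads lies in rows not used here. The CPM were divided by the smallest value above 0 in each library, and 100% of the values in every library came out as whole reads within 0.01 read. This gives 17.5 to 38.5 M reads in genes per library, where 1 M is the total to which CPM are scaled. At these depths 1 read is worth 0.0260 to 0.0571 CPM, so a gene at 1 CPM rests on about 17.5 to 38.5 reads, and values under 1 CPM carry a large counting error. Without molecular identifiers, reads are not independent molecules.

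The main test was limma 3.58.1 in R 4.3.3, with a variance trend, on log2(CPM + 1) without further scaling. Genes with at least 1 CPM in at least 5 libraries were tested, which kept 6833. Log2 differences are ON minus OFF on the log2(CPM + 1) scale and understate the change of genes near 1 CPM. Ratios are ratios of mean CPM. P-values are two-sided, adjusted by the Benjamini-Hochberg method over the 6833 genes, and a gene was called at an adjusted p under 0.05. For named genes an exact permutation test over the 252 assignments of the libraries was added, whose smallest two-sided p is 0.00794. The design had been written for CPM before the data were examined, and the unit was recorded as a signal only because repeated rows lift the column sums over the CPM total.

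The genes named in the text follow a rule fixed before the data were examined. They are glp-1, gld-1, gld-2, lst-1 and sygl-1, the 10 genes per direction with the largest log2 difference among called genes with a mean of at least 5 CPM in the higher group and no overlap between groups, up to 3 genes for each list with at least 5 tested members (called members first, by size of the difference, then uncalled members by level), and the called members of the list of reported Notch targets. Further members of a list are named where they describe its count. They were chosen after their values were seen.

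There were 23 gene lists, all fixed before the data were examined, covering the Notch pathway, reported Notch targets, RNA regulators of germline stem cells, meiotic prophase, DNA replication, mitosis, sperm, oocyte, germ granules and small RNAs, germline chromatin, sex determination, apoptosis, heat shock, somatic gonad, intestine, muscle, pharynx, cuticle, neurons, ribosomal proteins, histones, the mitochondrial genome and rRNA. The 20 lists with at least 5 tested members were compared with all other tested genes by camera in limma with a preset correlation of 0.01, adjusted over the 20 lists. Camera with an estimated correlation was an alternative. Fry, which tests a list against no change and not against other genes, was another, so its p-values answer a different question. Called genes on X and autosomes were compared by Fisher's exact test. Chromosomes and coordinates come from the Ensembl annotation of the WBcel235 assembly, matched by gene identifier (46363 genes matched), and say nothing about the build the authors used.

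The same procedure was tested on simulated counts built from the means, library sizes and dispersions of the 6833 genes, with 200 genes changed, in 5 runs. For this comparison it recovered 97.8% of the genes changed by 1 on the log2 scale and 100% of those changed by 2. False calls made up 5.42% of all calls, and 0 of 100 unchanged lists were called by camera. The simulated genes varied independently of each other, and the simulated libraries differed in size but not in composition. These error rates therefore need not hold for the real libraries, where genes are correlated and results depend on scaling.

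The alternatives were pseudocounts of 0.25 and 5 CPM, no filter or a filter of 5 CPM, TMM, median-ratio and quantile scaling, no variance trend, library weights, the replicate number or the set of library numbers in the model, a covariate for somatic markers, edgeR 4.0.16 (quasi-likelihood test) and DESeq2 1.42.0 on the recovered reads, a minimum difference of 1 on the log2 scale, and each library left out in turn. Scaling to reads outside rRNA genes, rRNA percent as a covariate, the omission of the 2 libraries with the largest single-gene spikes, and TMM together with the library number set were added after the data had been seen. The numbers in the column labels fall into 3 sets (56 to 58, 85 to 88 and 127 to 130). The labels do not call these sets batches, but each holds both groups, so differences within sets are given. The first set holds ON replicate 1 with OFF replicates 1 and 2. The second holds ON replicate 2 with OFF replicates 3 and 4. The third holds ON replicates 3 to 5 with OFF replicate 5. Each difference within a set therefore rests on a single library in 1 of the groups, and the groups are spread unevenly over the sets.

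Replicates of a group were compared only to see whether any of them repeated another. None did, as the mean chi-square statistic per gene lay between 16.2 and 233, values that single-library spikes raise and that say nothing on the quality of the replicates.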

Results

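Ribosome-depleted total RNA was sequenced from dissected germline tumours of C. elegans. All worms carried gld-2(q497) gld-1(q485), a double mutant in which germ cells fail to enter meiosis properly and keep dividing whether or not Notch signals. GLP-1, the germline Notch receptor, was kept active by glp-1(ar202), a gain-of-function allele, in 5 libraries (ON), and was removed by glp-1(q175), a null allele, in 5 libraries (OFF). The design therefore asks which transcripts depend on Notch signalling in germ cells that proliferate in both states. Library depth was 29.4 ± 8.61 M reads in genes in ON and 23.8 ± 4.08 M reads in OFF (SD, n = 5 each), with a range of 17.5 to 38.5 M reads.

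The libraries separated by GLP-1 state. The first principal component held 45.3% of the variance, with every ON library at or below -10.6 and every OFF library at or above 9.44. Despite depletion, rRNA genes took 44.6 ± 3.65% of reads in ON and 44.1 ± 5.10% in OFF (SD, n = 5), and ranged from 38.96% to 50.8% between libraries. The mean log2 level of somatic markers was 1.82 ± 0.203 in ON and 1.94 ± 0.114 in OFF (SD, n = 5), a difference within the spread of the libraries (exact permutation test, two-sided, p = 0.317, adjusted p = 0.556 over 7 library measures).

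The receptor gene and the best known germline outputs of the receptor were far higher in ON. Transcripts of glp-1 itself (chromosome III, 9092241 to 9099698, plus strand) were at 248 ± 28.2 CPM in ON and 88.2 ± 13.5 CPM in OFF (SD, n = 5), a ratio of 2.82. The groups carry different glp-1 alleles, so an effect of the alleles on their own transcript cannot be told apart from one of Notch signalling. The stem cell genes lst-1 (chromosome I, 10588501 to 10590465) and sygl-1 (chromosome I, 12483809 to 12486235) act downstream of GLP-1 to keep germ cells in the stem cell state. The lst-1 level was 33.6 ± 3.45 CPM in ON and 11.7 ± 2.27 CPM in OFF, a ratio of 2.88, and the sygl-1 level was 21.2 ± 6.27 CPM and 1.29 ± 0.370 CPM, a ratio of 16.42. For each of these genes all 5 ON libraries lay above all 5 OFF libraries (exact permutation test, two-sided, p = 0.00794, the smallest possible here). The limma log2 differences were 1.49 for glp-1 (adjusted p = 8.7e-09), 1.47 for lst-1 (adjusted p = 1.7e-08) and 3.24 for sygl-1 (adjusted p = 8.1e-12). Within the 3 sets of library numbers the difference was 1.47, 1.11 and 1.72 for glp-1, 1.48, 1.11 and 1.77 for lst-1, and 2.92, 2.81 and 3.51 for sygl-1.

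The background mutations left measurable transcripts of both gld genes. For gld-2, a cytoplasmic poly(A) polymerase, the level was 50.4 ± 7.64 CPM in ON and 53.7 ± 10.3 CPM in OFF (SD, n = 5), a log2 difference of -0.08 that did not pass the limma test (adjusted p = 0.714). For gld-1, an RNA-binding translational repressor, it was 62.6 ± 9.72 CPM and 49.7 ± 5.38 CPM, a log2 difference of 0.32 with a limma adjusted p of 0.0502. After TMM scaling the gld-1 difference was 0.36 with an adjusted p of 0.0081. It was 0.19, -0.09 and 0.64 within the 3 sets of library numbers.

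**Figure D1:**
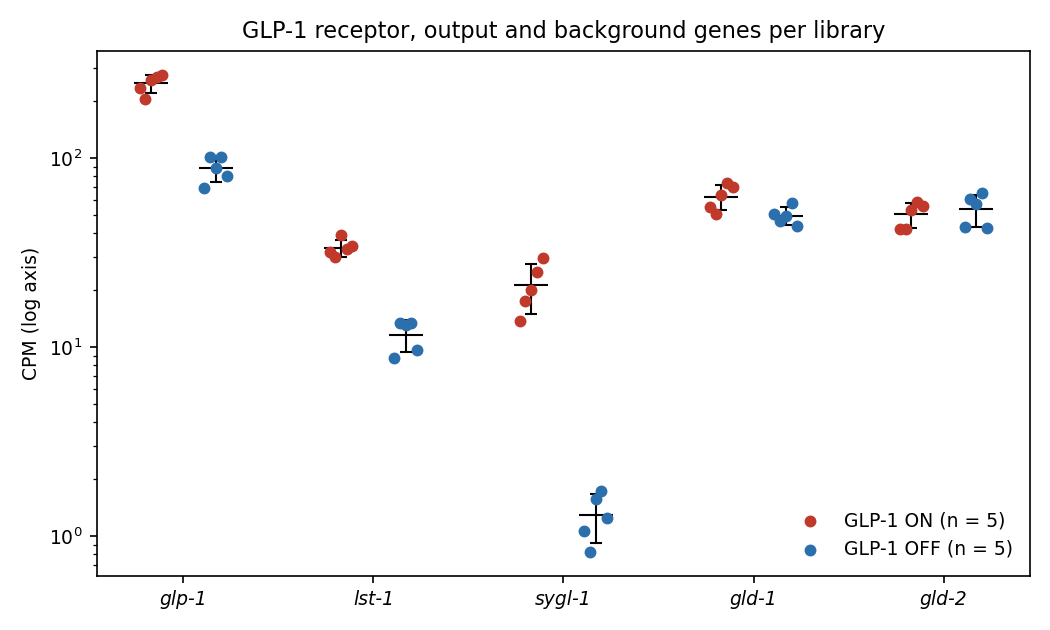
CPM of glp-1, lst-1, sygl-1, gld-1 and gld-2 (log axis) in each of the 5 ON and 5 OFF libraries, with the mean and SD of each group in black. The groups do not overlap for glp-1, lst-1 and sygl-1, with sygl-1 at 21.2 CPM in ON and 1.29 CPM in OFF, and they overlap for gld-1 and gld-2.

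Of 6833 tested genes, 458 were higher and 847 were lower in ON, so 35.1% of the calls were higher. Changes of at least 1 on the log2 scale were few and evenly split, with 54 higher and 51 lower, and all of these kept their sign in each of the 3 sets of library numbers. Of all calls, 431 higher and 822 lower genes kept their sign in each set. These counts are no independent support, because the calls were made on the same libraries. A gene without overlap between groups keeps its sign in every set. The groups did not overlap for 310 of the higher and 597 of the lower genes, and did not overlap for 14.9% of all tested genes, where chance gives 0.794%. The balance of the calls depended on library scaling. TMM scaling gave 1129 higher and 1247 lower genes (47.5% higher), median-ratio scaling 51.3% higher and quantile normalisation 50.9% higher, and 455 of the 458 and 825 of the 847 genes were also called with TMM.

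Apart from sygl-1, glp-1 and lst-1, genes with large increases had varied functions. Larger log2 differences than those of glp-1 and lst-1 were seen in bath-13, which encodes a BTB and MATH domain protein, at 13.2 ± 1.95 CPM in ON and 1.72 ± 0.319 CPM in OFF, and the autophagy gene epg-5, at 35.2 ± 5.95 CPM and 6.58 ± 2.52 CPM (SD, n = 5). The calpain gene tra-3, which acts in sex determination, was at 9.02 ± 1.70 CPM and 1.54 ± 0.204 CPM, a ratio of 5.87. The non-coding RNA F52D4.1 was at 198 ± 19.9 CPM and 55.9 ± 12.2 CPM. The cuticlin-like gene cutl-10 was 4.18 times and the pseudogene Y57G7A.8 was 3.76 times as abundant in ON. Limma adjusted p-values of these 6 genes ran from 7.7e-12 for bath-13 to 3.3e-08 for Y57G7A.8. The cadherin gene cdh-12 was also called (adjusted p = 0.0031), but its ON mean of 13.96 CPM rests on a level of 44.2 CPM in replicate 4, with the other 4 ON libraries at 4.31 to 7.83 CPM and an OFF mean of 2.51 CPM.

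The largest decreases included a histone cluster, described with the histones, and several genes with other functions. W07E11.1 on X was at 1.60 ± 0.310 CPM in ON and 29.5 ± 12.1 CPM in OFF (SD, n = 5), or 18.4 times higher in OFF. The small heat shock protein gene sip-1 was at 35.1 ± 8.12 CPM and 208 ± 28.96 CPM, a log2 difference of -2.55. The P granule gene pgl-2 was at 11.01 ± 0.420 CPM and 57.6 ± 8.12 CPM, a log2 difference of -2.28. The 14-3-3 gene ftt-2 and the cadherin gene cdh-4 were 5.42 and 5.17 times as abundant in OFF. In limma, adjusted p was 6.7e-11 for W07E11.1, 3.2e-11 for sip-1, 2.1e-12 for pgl-2, 2.7e-08 for ftt-2 and 2.2e-10 for cdh-4, and no ON library reached the level of any OFF library for any of them.

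Among core Notch components, 1 gene rose and 1 fell of 12 tested. Besides glp-1, whose alleles differ between the groups, the change was in sel-8, which encodes the Mastermind-like co-activator of the Notch complex. It fell to 12.9 ± 2.21 CPM in ON from 27.5 ± 4.03 CPM in OFF (SD, n = 5; limma adjusted p = 2.4e-06). The level of sel-10, an F-box gene that restrains Notch, was 80.9 ± 9.15 CPM and 78.9 ± 7.65 CPM and did not pass the test (adjusted p = 0.863). The counts adjusted over the list alone were also 1 and 1. After TMM scaling 2 rose and 1 fell, as the Notch transcription factor gene lag-1 was then also called (log2 difference 0.29, adjusted p = 7.9e-04, against 0.25 and 0.120 without scaling), and the list as a whole did not stand apart from other genes (camera adjusted p = 0.389).

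Of the genes reported as Notch targets in any C. elegans tissue, 8 were expressed at a testable level, 3 rose and 1 fell. The phosphatase gene lip-1 rose with lst-1 and sygl-1, from 1.43 ± 0.292 CPM in OFF to 3.15 ± 1.22 CPM in ON (SD, n = 5; limma adjusted p = 0.0018). The sorting nexin gene lst-4 fell, from 69.1 ± 9.21 CPM to 48.8 ± 4.96 CPM (adjusted p = 0.0027). Adjusted over the list alone, 5 rose and 1 fell, as after TMM scaling. The list passed camera with the preset correlation (adjusted p = 8.4e-04), but not with an estimated correlation (adjusted p = 0.926).

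RNA regulators of stem cell fate and meiotic entry moved both ways, with 3 higher and 4 lower of 19. Besides lst-1 and sygl-1, gls-1, which encodes a partner of GLD-3, rose to 134 ± 21.9 CPM from 98.3 ± 18.4 CPM. The F-box gene prom-1, which promotes meiotic entry and chromosome pairing, fell to 24.4 ± 3.16 CPM from 48.0 ± 6.67 CPM (limma adjusted p = 2.6e-06). The PUF family genes fbf-1, puf-3 and puf-11 fell by a log2 difference of -0.34, -0.35 and -0.36. With p adjusted over the list alone, 4 rose and 4 fell, and after TMM scaling 5 and 4. The list did not pass camera (adjusted p = 0.207).

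Of the 23 lists, genes of meiotic prophase had the most decreases in ON by count. Shares were not compared between lists, and 9 of 28 oocyte, 8 of 24 histone and 3 of 9 sperm genes also fell. Among all 6833 tested genes 847 fell. Of 47 tested meiotic prophase genes, 17 fell and 0 rose (limma at an adjusted p under 0.05). TMM scaling and the edgeR test each called 22 lower and 3 higher. The count adjusted over the list alone was 20 lower and 0 higher. All the HORMA domain genes of the chromosome axis fell. The level of htp-3 was 113 ± 12.6 CPM in ON and 199 ± 23.3 CPM in OFF, that of him-3 was 44.4 ± 3.20 CPM and 75.8 ± 4.91 CPM, and those of htp-1 and htp-2 were 1.57 and 1.56 times higher in OFF (SD, n = 5). Among genes of the synaptonemal complex, syp-1 fell from 17.8 ± 2.84 CPM to 10.1 ± 1.17 CPM, and syp-2, syp-4 and F57B10.4 (syp-6 in current names) were 1.27, 1.501 and 1.55 times higher in OFF. The meiotic cohesin genes coh-3 and coh-4, the double-strand break genes dsb-1 and dsb-2, the kinase gene chk-2, zim-2, rad-54, C17E4.4 (mjl-1 in current names) and prom-1 completed the 17, with log2 differences from -0.31 for coh-3 to -0.95 for prom-1. The gene for the break-making enzyme, spo-11, and rad-51 were among the 30 genes without a call. The pairs htp-1 and htp-2, and coh-3 and coh-4, are close paralogs whose reads may be divided between copies, so their separate values are uncertain. The median of the list lay 0.13 below that of all tested genes (relative log2 difference -0.13, camera adjusted p = 8.4e-04). With an estimated correlation the adjusted p = 0.926. After TMM scaling, camera gave an adjusted p of 6.9e-04 with the preset correlation and 0.0532 with an estimated one, which is above the threshold. The directional fry test asks whether the genes of the list moved together in 1 direction, without comparison with other genes. It gave an adjusted p of 0.0969. The mixed fry test, in which genes may move either way, gave an adjusted p of 4.5e-05.

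**Figure D2:**
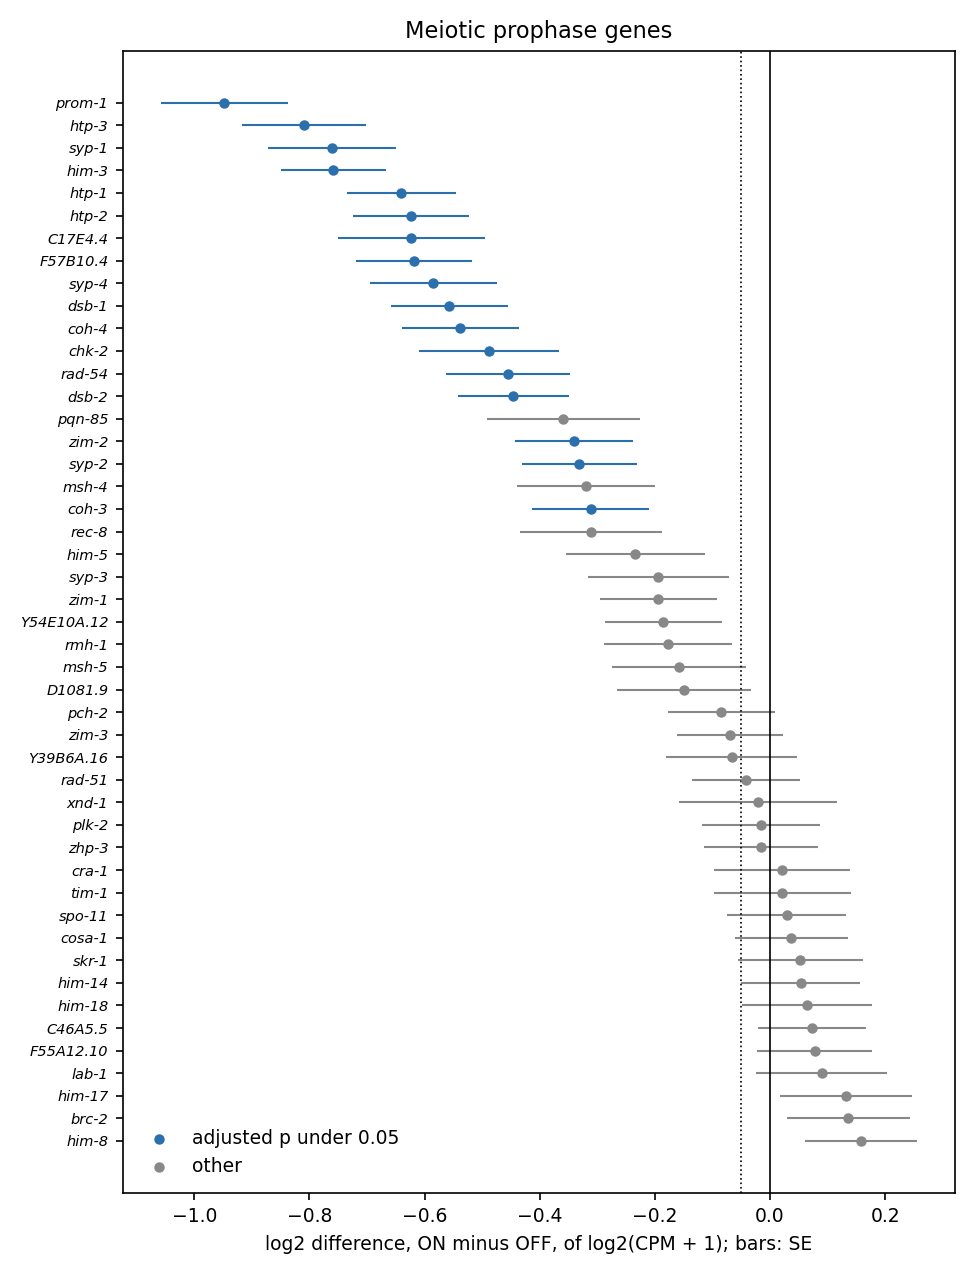
Log2 difference (ON minus OFF, x axis, on the log2(CPM + 1) scale) of the 47 tested meiotic prophase genes, with SE bars from limma, n = 5 per group. Genes with an adjusted p under 0.05 are blue, others grey, the solid line marks 0 and the dotted line the median of all tested genes, -0.05. The 17 blue genes all lie to the left of 0, from coh-3 at -0.31 to prom-1 at -0.95.

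Most genes of DNA replication and mitosis did not pass the test, as 31 of 35 and 35 of 39 had no call. After TMM scaling 7 replication genes were lower and 2 higher, and 8 mitotic genes were lower and 4 higher. In replication, the GINS gene psf-1 fell from 30.8 ± 2.02 CPM to 19.7 ± 1.16 CPM, and the cell cycle regulators cdk-2 and cki-2 were 1.47 and 1.65 times higher in OFF (SD, n = 5). The origin recognition gene orc-1 rose from 79.4 ± 11.7 CPM to 99.2 ± 8.15 CPM. The 4 mitotic genes that fell were those for the kinase cdk-1 and the B-type cyclins cyb-1, cyb-2.1 and cyb-2.2. The cyb-1 level was 76.3 ± 11.4 CPM in ON and 122 ± 16.43 CPM in OFF (limma adjusted p = 3.3e-04). When adjusted over the list alone, 3 replication genes fell and 0 rose, and 4 mitotic genes fell and 0 rose. Neither list passed camera (adjusted p = 0.409 for replication and 0.389 for mitosis).

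Of 28 tested oocyte genes 18 had no call, 9 were lower and 1 was higher in ON. The eggshell chondroitin proteoglycan gene cpg-1 fell from 145 ± 20.2 CPM to 67.6 ± 13.8 CPM (SD, n = 5; limma adjusted p = 3.8e-06). The oogenesis regulator lin-41 fell from 57.0 ± 8.79 CPM to 35.98 ± 6.17 CPM and the eggshell gene perm-2 from 52.9 ± 6.10 CPM to 35.2 ± 4.75 CPM, while mex-6 rose from 14.97 ± 3.36 CPM to 21.8 ± 4.79 CPM. Adjusted over the list alone, 13 fell and 1 rose, and after TMM scaling 11 fell and 3 rose. The list passed camera (adjusted p = 0.028), but not with an estimated correlation (adjusted p = 0.926) nor without ON replicate 1 or 2 or OFF replicate 3 or 4 (adjusted p from 0.057 to 0.073). Only 9 sperm genes were testable. Of these 3 fell, cpb-1, spe-44 and spe-6, and spe-9 rose from 0.470 ± 0.149 CPM to 1.63 ± 0.435 CPM (adjusted p = 7.2e-05). In the sperm list 5 fell and 1 rose when adjusted over the list alone, and 5 fell and 2 rose after TMM scaling (camera adjusted p = 0.389).

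Germ granule and small RNA genes were mostly without a call, with 3 lower and 0 higher of 35. Apart from pgl-2, the falls were in the argonaute gene wago-4, from 203 ± 21.1 CPM to 128 ± 25.3 CPM, and the RNA-dependent RNA polymerase gene rrf-1, from 110 ± 16.52 CPM to 77.8 ± 6.19 CPM (SD, n = 5). Among 21 germline chromatin genes, hpl-2 (44.8 ± 3.50 CPM in OFF and 32.7 ± 1.70 CPM in ON) and lin-61 (78.0 ± 6.77 CPM and 60.8 ± 2.96 CPM) fell and 0 rose. In sex determination, tra-3 and sdc-1 rose and fog-2 fell, of 15 tested. The cell death genes ced-3 and ced-4 fell, by log2 differences of -0.39 and -0.41, and 0 of the 14 apoptosis genes rose. The calls of fog-2 and ced-3 were lost in some of the fits that left out a library. These 4 lists, each adjusted over the list alone, gave 3, 2, 1 and 2 lower and 0, 0, 2 and 0 higher. After TMM scaling they gave 7, 3, 1 and 5 lower and 4, 4, 5 and 1 higher, so these counts depend on the scale. None of them passed camera (adjusted p = 0.568, 0.843, 0.131 and 0.565).

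The histone list split sharply. Of 24 tested histone genes, 8 fell and 5 rose in ON. The neighbouring genes his-1 to his-4 on chromosome V (16040144 to 16042831) and his-31 and his-32 on chromosome IV (8333672 to 8334715) summed to 9.12 ± 1.72 CPM in ON and 93.8 ± 16.7 CPM in OFF (SD, n = 5). For his-3 the level was 1.01 ± 0.165 CPM in ON and 22.1 ± 2.79 CPM in OFF (limma adjusted p = 2.3e-15), and for his-32 it was 5.08 ± 0.989 CPM and 31.8 ± 4.01 CPM. The other falls were in his-6 and his-16. Among abundant copies, his-59, his-60, his-61, his-67 and his-68 rose, with his-59 at 2405 ± 534 CPM in ON and 1612 ± 127 CPM in OFF. All of these calls kept their direction under TMM scaling. There were 10 falls and 5 rises adjusted over the list alone. The list passed camera (adjusted p = 0.015), not with an estimated correlation (adjusted p = 0.926), nor after TMM scaling (adjusted p = 0.144). Genes for the same histone type can be near-identical copies, so the reads of such copies are uncertain.

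**Figure D3:**
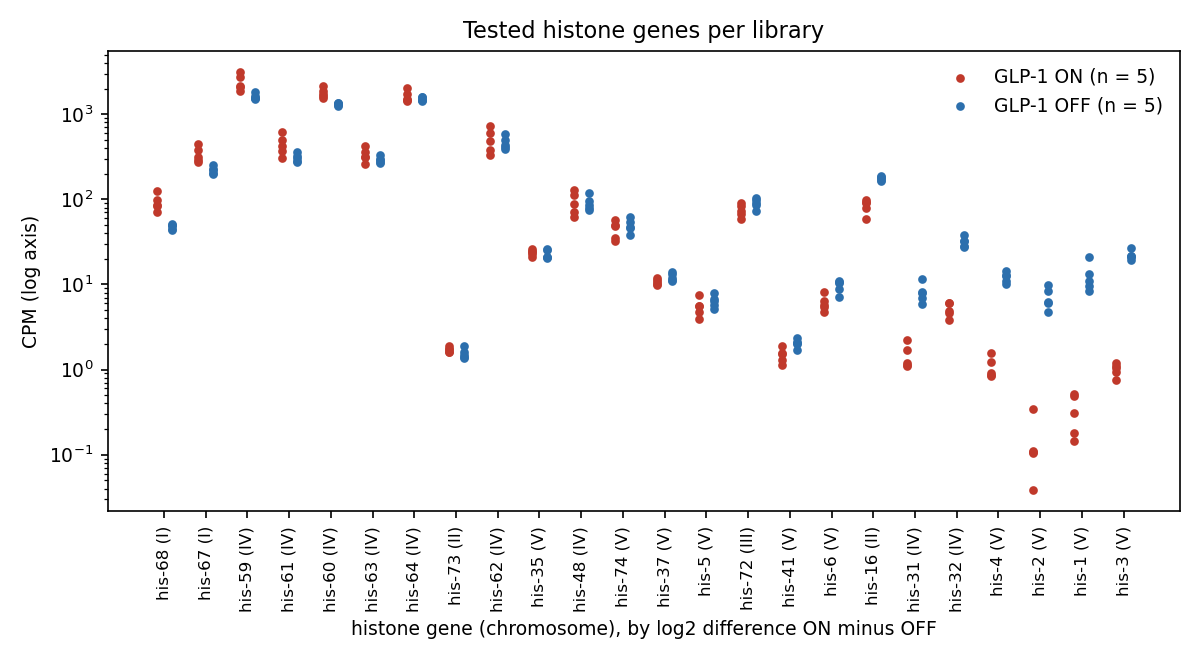
CPM (log axis) of the 24 tested histone genes in each of the 5 ON (red) and 5 OFF (blue) libraries, ordered by log2 difference, with the chromosome in brackets. At the right, his-31, his-32 and his-1 to his-4 are lower in every ON library than in any OFF library, while his-59, at 2405 CPM in ON and 1612 CPM in OFF, stands among the genes that rose.

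Most genes of ribosomal proteins and of the mitochondrial genome had no call, as was so for 74 of 79 and 11 of 14. Of 79 ribosomal protein genes 5 rose and 0 fell (23 rose after TMM scaling), and the median lay 0.14 above that of all tested genes on the log2 scale. The level of rpl-41.2 was 1042 ± 78.5 CPM in ON and 739 ± 72.9 CPM in OFF, and that of rps-2 was 1381 ± 145 CPM and 1039 ± 169 CPM (SD, n = 5). The list passed camera (adjusted p = 6.9e-05), not with an estimated correlation (adjusted p = 0.926) nor after quantile normalisation (adjusted p = 0.446). Of the 14 genes of the mitochondrial genome, nduo-6, ctb-1 and nduo-1 rose and 0 fell, with ctb-1 at 1788 ± 95.3 CPM and 1329 ± 231 CPM. That list passed camera (adjusted p = 0.0037), not with an estimated correlation (adjusted p = 0.926) nor after TMM scaling (adjusted p = 0.059). For ribosomal proteins 2 genes and for mitochondria 3 genes rose, and 0 fell, adjusted over the list alone. Among 10 heat shock genes, the chaperone genes hsp-1 and daf-21 (hsp-90 in current names) rose by 0.55 and 0.42 on the log2 scale, though not within the second of the 3 sets of library numbers (-0.21 and -0.01, against 0.50 and 0.41 in the first and 0.95 and 0.65 in the third) and with overlap between groups (exact permutation test, two-sided, p = 0.0556 and 0.0159), and the endoplasmic reticulum chaperone gene hsp-4 fell from 292 ± 40.9 CPM to 192 ± 24.6 CPM. The calls of rps-2, nduo-6, nduo-1, hsp-1 and daf-21 were each lost in at least 1 fit that left out a library. Adjusted over the list alone, and also after TMM scaling, 3 rose and 1 fell (camera adjusted p = 0.214). Of 5 tested rRNA genes 0 were called by limma, by edgeR or after TMM scaling, nor when adjusted over the list alone (camera adjusted p = 0.813). The most abundant gene in every library was rrn-2.1, at 31.001% to 43.3% of reads.

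Most markers of the surrounding body were at low levels. Summed levels in ON and OFF were 10.6 ± 1.76 and 15.7 ± 5.32 CPM for all intestine genes of the list, tested or not, 48.6 ± 16.12 and 57.2 ± 9.83 CPM for muscle, 8.34 ± 1.52 and 10.7 ± 1.08 CPM for cuticle, 37.8 ± 4.85 and 42.2 ± 13.2 CPM for neurons, and 6.20 ± 1.85 and 28.7 ± 50.1 CPM for the pharynx (SD, n = 5), where phat-4 alone was at 111 CPM in OFF replicate 2. Among them lbp-6 of the intestine, lev-11 and mup-2 of muscle and dpy-17 of the cuticle fell. The neuronal gene unc-31, which acts in dense core vesicle release, rose from 0.481 ± 0.134 CPM to 4.18 ± 0.668 CPM (limma adjusted p = 4.3e-10), as the only call among 5 neuronal genes. In the somatic gonad list lim-7 and ina-1 fell, of 7 tested, and both calls were lost in at least 1 fit that left out a library. Adjusted over the list alone, 4 somatic gonad genes, 2 muscle genes, 1 intestine gene and 1 cuticle gene fell, and 1 neuronal gene rose. After TMM scaling the same counts held except for muscle, where 4 genes fell. Camera adjusted p was 0.141 for the somatic gonad, 0.189 for muscle and 0.265 for neurons, and intestine (3 genes), cuticle (4 genes) and pharynx (2 genes, 0 called by limma, edgeR or after TMM scaling) were too small for it.

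Genes on the X chromosome were called higher in ON more often than autosomal genes. Of 211 tested X genes 34 were higher (16.114%), against 420 of 6597 on autosomes (6.37%), an odds ratio of 2.82 (Fisher's exact test, two-sided, p = 1.4e-06, adjusted p = 2.9e-06 over both directions). Lower calls were 21 on X (9.95%) and 826 on autosomes (12.5%), an odds ratio of 0.77 (Fisher's exact test p = 0.291). After TMM scaling the excess of higher calls was no longer past the threshold (odds ratio 1.23, Fisher's exact test p = 0.258), and lower calls were fewer on X than on autosomes (odds ratio 0.46, p = 3.9e-04). With no filter on low values the odds ratio of a higher call was 0.73 (Fisher's exact test p = 0.031). Genes are not independent of each other, so these p-values are descriptive.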

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

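The tests of library scaling, of histone genes in general and of shared reads for the histone genes, and of GLP-1 state for the spikes, were chosen after those results had been seen, and the other tests in this part were set before their results were seen. Of 152 groups of 5 libraries checked for a library far from the others, 5 had such a library, where chance alone gives about 7.6. The cdh-12 level in ON replicate 4 was 44.2 CPM, with the other ON libraries at 4.31 to 7.83 CPM. In the same library his-2 was at 0.343 CPM, with the others at 0.0381 to 0.109 CPM. The ftt-2 level in OFF replicate 5 was 9.50 CPM, with the others at 16.24 to 19.7 CPM. The lin-61 level in OFF replicate 2 was 89.9 CPM, with the others at 73.5 to 77.0 CPM. The lev-11 level in OFF replicate 4 was 4.88 CPM, with the others at 2.49 to 3.04 CPM.

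Real calls were more numerous than in other splits of the 10 libraries. Of 100 splits into 5 and 5 drawn from the 126 possible, with the real one always kept, only the real split gave as many as its 1305 genes. A share of 1 in 100 is the smallest this test can give. Chance is thus made less likely as the source of the count, but it is not excluded. The highest other split gave 1170 genes. It put ON replicates 1 and 2 with OFF replicates 1, 3 and 5, and its sides differed in mean rRNA share (47.3% against 41.4% of reads), which points to a structure of the samples on the deposited scale. After TMM scaling that split gave 0 genes, the real split 2376 and the highest other split 332, and again only 1 of 100 splits, the real one, reached the real count.

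The histone genes his-1 to his-4, his-31 and his-32 were 5.48 to 50.2 times more abundant in OFF by mean CPM, with no overlap between groups. Library scaling does not account for this, as all 6 stayed lower in ON with TMM scaling. A lower share of cells in S phase would lower replication-dependent histone genes in general. The median log2 difference of the 18 other tested histone genes was 0.069 (0.11 after TMM scaling), with 5 higher and 2 lower, so no general fall was seen among them. These 18 genes were not sorted by dependence on replication, and their reads may be shared between copies, which limits what this median can say about S phase. What stays open is how reads shared by near-identical copies were counted: 48 of 72 histone genes did not pass the filter, and the summed level of the other 66 genes was 1657 CPM higher in ON by mean, a difference that was not tested and is far larger than the one in the 6 genes, so a shift of reads between copies or a sequence variant in 1 of the strains cannot be told apart from lower transcription of these copies. A direct effect of GLP-1 on these copies is the biological alternative, and it was not tested.

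In 25 genes a single library reached at least 10 CPM and more than 5 times every other library, as cdh-12 did in ON replicate 4. The highest were iglr-3 in OFF replicate 3 (50639 CPM, next library 5.95 CPM) and frm-2 in ON replicate 1 (7631 CPM, next library 1.61 CPM), and of the 5 that passed the filter and were tested only cdh-12 was called. The iglr-3 spike held 1321560 of the 26.1 M reads in genes of OFF replicate 3, which lowers the CPM of the other genes there. A raised chromosome segment is argued against, because 0 of the 24 spikes with a known position had a spiking gene within 2 genes on either side, and for phat-4 in OFF replicate 2 (111 CPM) pharyngeal gland cells are argued against, because the other 5 phat genes were at 0 CPM there. The spikes lay in 9 of the 10 libraries, with 9 in ON and 16 in OFF (exact binomial test, two-sided, p = 0.230), too few to tell whether GLP-1 state matters. Amplified fragments or carry-over of a cloned or PCR product during library preparation may explain spikes of this kind, which the gene totals cannot show (0 neighbouring spikes).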

How the results depend on the processing

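The scaling to non-rRNA reads, the rRNA percent covariate, the omission of both spike libraries, and TMM with the library number set, were chosen after seeing the data. The test on separate columns of another unit was not run, because the table holds 1 unit. Of the 60 called named genes, 48 kept direction and call under every alternative in which they were tested, left-out libraries included. Of the 60, 11 did not pass the filter of 5 CPM and so were not tested there, and cdh-12 also had no adjusted p in DESeq2. Calls were lost under at least 1 alternative for spe-44, lin-61 and ctb-1, and also with at least 1 library left out for fog-2, ced-3, hsp-1, daf-21, ina-1, lim-7, rps-2, nduo-6 and nduo-1. In all 28 settings glp-1, lst-1 and sygl-1 stayed called, gld-1 was called in 16 (log2 difference 0.26 to 0.42) and gld-2 in 0. At this depth a gene at 1 CPM rests on about 17.5 to 38.5 reads, so its counting error is large.

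The number of genes higher in ON was 458. It was 1129 with TMM scaling, 1219 with median-ratio scaling, 1248 with quantile normalisation, 1177 with array weights, 827 with the somatic marker covariate, 1145 with edgeR and 1323 with DESeq2 on recovered reads (5 genes without an adjusted p), 874 with scaling to non-rRNA reads, 980 with the rRNA percent covariate, 1012 with TMM and the library number set, 221 with a filter of 5 CPM (fewer genes were tested) and 54 with a log2 difference of at least 1. The number of genes lower in ON was 847, 1344 with scaling to non-rRNA reads, 1534 with the rRNA percent covariate and 51 with a log2 difference of at least 1. Without the spike libraries the counts were 325 and 566. With the library number set in the model they were 356 and 635, of which 340 and 610 were also called in the main fit. Leaving out each library gave 353 to 641 genes higher and 625 to 1067 lower, and without OFF replicate 2 the split was 641 and 683. That rRNA share sets part of the scale is in line with these counts, and the cause was not tested further.

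The replicate block gave 517 higher and 1028 lower genes. Whether the replicate numbers pair the samples is not settled, and the labels do not say that they do. Deviations of same-numbered libraries correlated at 0.24, -0.02, 0.23, 0.46 and 0.17, and 3 of 5 ON libraries correlated best with their own number. The block ended no call among named genes or lists and added 2 named calls, gld-1 and inx-8.

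Of the 6 lists called, 4 were called with TMM scaling, 1 with quantile normalisation and 0 with an estimated correlation. Directional fry, which tests a list against no change and not against other genes, called 3 lists, reported_notch_targets, histones and neuron. The last was not among the 6. For reported_notch_targets the median relative to all genes was 0.33 with an estimated correlation (adjusted p = 0.926) and 0.32 with quantile normalisation (adjusted p = 0.058), and for meiotic_prophase it was -0.13 with an estimated correlation (adjusted p = 0.926), where the construction changes the test and not the value. The meiotic_prophase list was not called by directional fry (adjusted p = 0.097), but it was by mixed fry (adjusted p = 4.5e-05). After TMM scaling, camera with an estimated correlation gave it an adjusted p of 0.0532. Leaving out each library gave medians of 0.29 to 0.38 for reported_notch_targets and -0.15 to -0.12 for meiotic_prophase, all called. The oocyte list lost its call in 9 settings, among them those without ON replicate 1 or 2 or OFF replicate 3 or 4 (adjusted p 0.057 to 0.073).

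The odds ratio of a higher call for genes on X was 0.73 with no filter, 1.23 with TMM scaling, 1.11 with median-ratio scaling, 1.11 with quantile normalisation, 1.17 with array weights, 1.28 with edgeR, 1.10 with DESeq2, 1.15 with TMM and the library number set and 1.85 with a log2 difference of at least 1, and 1.69 to 3.66 with each library left out. The odds ratio of a lower call was 0.27 with no filter, 1.33 with a filter of 5 CPM, 0.46 with TMM scaling, 0.50 with median-ratio scaling, 0.45 with quantile normalisation, 0.52 with edgeR, 0.45 with DESeq2, 0.48 with scaling to non-rRNA reads, 0.61 with the rRNA percent covariate, 0.56 with TMM and the library number set, 1.15 without the spike libraries and 1.97 with a log2 difference of at least 1. With each library left out it was 0.67 to 1.17, above 1 without ON replicate 1 (1.17) or ON replicate 5 (1.15). The cause was not tested for these values.

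Log2 differences that changed sign were those of 7 named genes without a call, all close to 0, and none was called in either direction. For gld-2 it was 0.059 with the somatic marker covariate and 0.0026 without the spike libraries. For sel-10 it was -0.011 with the library number set, and -0.019 to 0.087 with each library left out. For let-418 it was 0.077 with the somatic marker covariate, and -0.17 to 0.0011 with each library left out. For unc-104 it was 0.0056 with array weights, 0.0069 with the somatic marker covariate and 0.0035 with DESeq2, and -0.13 to 0.023 with each library left out. For rrn-2.1 it was -0.075 with the somatic marker covariate, -0.0075 with the rRNA percent covariate and -0.028 without the spike libraries, and -0.049 to 0.072 with each library left out. For rrn-3.1 it was 0.045 with the somatic marker covariate and 0.17 without the spike libraries, and -0.32 to 0.17 with each library left out. For rrn-4.15 it was 0.015 with TMM scaling, 0.026 with median-ratio scaling, 0.051 with quantile normalisation, 0.037 with the somatic marker covariate and 0.26 without the spike libraries, and -0.17 to 0.18 with each library left out. The cause was not tested.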

Other observations

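The snRNA and tRNA genes took a smaller share of reads in ON, and the snoRNA genes did not differ detectably. Of 20 tested snRNA genes, 8 fell and 2 rose, and snRNA genes together took 0.129 ± 0.0151% of reads in ON and 0.196 ± 0.0406% in OFF (SD, n = 5, exact permutation test, two-sided, p = 0.00794, adjusted p = 0.0278 over 7 RNA classes). Of 7 tested tRNA genes 3 fell and 0 rose (limma, and also 3 and 0 after TMM scaling), with 0.00469 ± 0.000536% and 0.00747 ± 0.00171% of reads (p = 0.00794, adjusted p = 0.0278, exact permutation test). Of 128 snoRNA genes 20 fell and 10 rose (14 and 8 after TMM scaling), with 2.16 ± 0.118% and 2.29 ± 0.307% of reads (exact permutation test p = 0.421, adjusted p = 0.589). A loss of short RNAs in rRNA depletion and library preparation was not separated here from a change in the cells.

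Several large changes lay in neighbouring genes. Besides the histone clusters, the p38 kinase genes pmk-3, pmk-2 and pmk-1 on chromosome IV (8139219 to 8151266) were all lower in ON, with pmk-3 at 2.52 ± 0.445 CPM in ON and 6.55 ± 1.35 CPM in OFF (SD, n = 5). So were C27D8.3, C27D8.2 and C27D8.1 on chromosome IV (12706700 to 12719395), with C27D8.3 at 10.9 ± 2.04 CPM and 44.3 ± 10.2 CPM. F56A12.11, F56A12.5 and F56A12.6 on chromosome V (14359109 to 14362451), and the nuclear receptor genes nhr-95 and nhr-145, were higher in ON, with nhr-145 at 4.90 ± 0.506 CPM and 0.621 ± 0.229 CPM. These genes were chosen after their values were seen.

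The test of placement and that of linkage to glp-1 were chosen after the neighbouring genes had been seen. Among the 105 genes with a called change of at least 1 on the log2 scale, 14 pairs of neighbouring tested genes changed the same way. In 10000 random placements the mean was 0.797 pairs and the highest number 7 (permutation p = 1e-04, the smallest these can give), so chance placement is argued against. Linkage to the glp-1 alleles on chromosome III would mean that other variants near glp-1 differ between the strains. It is argued against as the main source, since only 21 of the 105 large changes lay on III. The odds ratio of a large change there was 0.86 (95% interval 0.50 to 1.405, Fisher's exact test). This test took the chromosome as a whole and not the distance from glp-1. Linkage therefore stays open for single genes near glp-1, such as pgl-2 (chromosome III, 8670543 to 8675435). Large changes made up 0.615% of tested genes on chromosome I, against 1.83% on the other nuclear chromosomes (Fisher's exact test, adjusted p = 0.0012). On chromosome V they made up 2.82%, against 1.32% on the others (Fisher's exact test, adjusted p = 0.0034). Neighbouring genes that changed together, such as his-1 to his-4 on V, were counted separately, so these p-values are descriptive. Shared regulation of neighbours, reads of overlapping genes counted for both, and strain variants elsewhere in the genome may each produce such pairs (14 observed), and these stay open.

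X-linked genes may be shifted slightly towards ON as a set, beyond the calls, and the tests of this were set before their results were seen. The median log2 difference of the 211 X genes exceeded that of the 6597 autosomal genes by 0.07 (permutation p = 5e-04). Library scaling does not account for all of the shift, which was 0.053 after TMM scaling (permutation p = 0.0046), 0.048 after median-ratio scaling (p = 0.0114) and 0.040 after quantile normalisation (p = 0.027), although it makes the shift smaller and moves the calls from an excess of higher genes to a lack of lower ones. Low expression of X genes is argued against, because the X median was at percentile 100 of 10000 autosomal sets matched on level (median of these sets -0.08). With the somatic marker covariate the shift was 0.088 (permutation p = 1e-04, the smallest these permutations can give). That covariate holds the intestine, muscle, pharynx, cuticle and neuron lists, mostly at low levels, and leaves out the somatic gonad list. The shift thus remained after adjustment for these body markers, but RNA of the somatic gonad was not tested as its source. Genes are not independent of each other and the shift is small, so its cause stays open.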
